A study of Mus musculus with 3 samples.

How the data were processed

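Small RNA libraries were prepared from total RNA of mouse fibro/adipogenic progenitors with Illumina's TruSeq small RNA kit, per the labels' protocols. The progenitors were isolated from muscle and not cultured. The labels assign 1 library to each of 3 conditions, which are normal muscle, muscle after cardiotoxin and muscle after sciatic denervation. The time of 5 days after cardiotoxin was read from the title CTXD5-FAPs and the column header ctxD5. That of 3 weeks after denervation was read from the column header DN3W. How the progenitors were isolated, the number of animals behind a library, the aligner, the miRBase release and the genome build are not given in the sources used here. StringTie is named in the submitters' processing notes, with no version or role.

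The deposited table gave an estimated count per miRNA row and library, marked as raw per the file headers. Between 87.9% and 88.4% of these values were whole numbers within a tolerance of 1e-06. The others were fractions, and the rule that gave them is not given in the sources used here. The table held 1108 rows, of which 670 carried a mature mouse miRNA name, 58 a mouse hairpin name, 252 the name of a miRNA of another species and 128 a name starting with PC. 3 lines of the table were emptied for this work and are not analysed here. The deposited table also gave a normalized signal, which equalled the estimated count times 1 factor per library (1.11 for normal, 1.12 for cardiotoxin and 0.746 for denervated). How the authors set these factors is not given in the sources used here. The authors' deposited table held a chi-square p-value per row over the 3 libraries, which was under 0.05 for 1009 rows and 0.05 or more for 99. That test compares reads of these libraries, not conditions, and was not used further. A second deposited sheet listed normalized signals of 21 miRNAs in normal and denervated, all lower in denervated. These were exactly the rows at 24498 or more in normal that were lower in denervated.

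Rows with the same mature mouse name were summed, which concerned 7 names and left 1097 items. Each count was divided by the library's total over all rows and expressed as counts per 1000000 counts (CPM). Ratios between libraries were taken as log2 of CPM plus a pseudocount of 1, and folds were taken from CPM without it. Items with a mean of at least 10 CPM over the 3 libraries were kept, which left 446 items, 364 of them mature mouse miRNAs. An item counted as higher or lower when its log2 ratio reached 2-fold. With 1 library per condition there was no replicate and no spread between animals, so no test between conditions was run and no p-value was computed. Each fold has a 95% interval from the exact conditional binomial (Clopper-Pearson) method on counts rounded to whole numbers. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules. A fold against a library with a count of 0 was computed against 3 counts in that library and is given as a lower bound. This bound is not the end of a 95% interval, which allows smaller folds. For miR-205-5p in cardiotoxin against normal, at least 554-fold lower by the bound, the interval of the ratio reached 0.00222.

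24 lists with 224 entries were fixed before the data were examined, covering cell types that muscle holds and miRNA families or clusters linked to fibrosis, adipogenesis, inflammation and proliferation. The lists were muscle fibre, endothelial, leukocyte, erythroid, neural and glial, epithelial, smooth muscle and pericyte, mesenchymal, miR-29, pro-fibrotic, miR-17-92 with its paralogous clusters, miR-15/16, the miR-322, miR-503 and miR-351 cluster, let-7, miR-30, miR-23/27/24, inflammation, adipogenesis-promoting, adipogenesis-restraining, miR-221 and miR-222, miR-181, miR-34, H19 and Igf2 hosted, and Dlk1-Dio3. Lists with at least 3 kept members were placed by the percentile of their median log2 ratio among 10000 random lists of equal size, matched on mean level by decile. These percentiles describe the libraries and are not tests of the conditions. Random lists were drawn miRNA by miRNA, whereas arms of a hairpin and members of a genomic cluster tend to share ratios. Extreme percentiles of such lists therefore count related members apart. Some miRNAs also stand on several lists, such as miR-155-5p on the leukocyte, inflammation and adipogenesis-restraining lists. Results of different lists are therefore not independent. The miRNAs named in the text followed a rule set before the data were examined. It took, from the 200 mature mouse miRNAs with the highest mean, the 12 highest and 12 lowest ratios against normal and the 6 highest and 6 lowest between cardiotoxin and denervated, if at least 2-fold apart with an interval excluding 1. It added the 5 most abundant miRNAs of each library and up to 4 members per list with the highest mean. Other miRNAs named, such as miR-223-5p, miR-511-3p, miR-18a-5p, miR-31-5p, miR-130a-3p, miR-10b-3p and members of genomic clusters, were chosen after their values were seen.

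Positions come from an exact match of the row's sequence to miRNA genes of GENCODE M21 on GRCm38, which found 333 of the 364 kept mature names, 300 of them at a single gene. After the data were seen, kept miRNAs placed between the Dlk1 and Dio3 genes but absent from the fixed list were counted apart. 21 sequences appeared in several rows, always with equal counts. The rows named miR-99a-5p and miR-100-5p held a single sequence, which matched the miR-99a gene only, so the table gave no separate level of miR-100-5p. Whether the reads of such a sequence were split between its rows or counted in each is not given in the sources used here. miR-199b-3p has the same sequence as miR-199a-3p. The miR-133b-3p row's sequence also matched both miR-133a genes, so its reads could be shared with miR-133a-3p.

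The ratio and list scripts were tested on simulated Poisson counts with known folds. Simulated items were scored only with a mean of at least 10 CPM over both simulated libraries, and changed items below it were left out. For cardiotoxin against normal, all 37 scored 4-fold increases, all 27 decreases of 4-fold and all 30 increases of 3-fold were recovered. Of the scored decreases of 3-fold, 24 of 25 were recovered, with 0 of 310 unchanged items called. For denervated against normal, all 36, 27, 30 and 31 changed items in the same order were recovered, with 0 of 308 unchanged items called. The intervals held the true fold for 94.9% and 95.8% of items. Of 100 unshifted lists of 8, 4 fell beyond percentiles 2.5 and 97.5, and a list shifted by 1.5 on the log2 scale reached percentile 100. Counting noise alone, drawn 1000 times, gave a mean of 0.41 items at least 2-fold apart for cardiotoxin against normal and 0.14 for denervated against normal.

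Alternatives planned before the data were examined were TMM factors (edgeR 4.0.16), size factors (DESeq2 1.42.0), the authors' normalized signal, the total without the 5 miRNAs of highest mean, pseudocounts of 5 and 0.1, no filter, a mean of at least 100 CPM, the highest row of a name in place of the sum, and mature mouse names only. A total without miR-21a-5p, a filter on the normal and denervated libraries alone, and the mesenchymal list without the miR-100-5p row were added after the data were seen. edgeR and DESeq2 were used for scaling only, on the counts rounded to whole numbers. Other work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3.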

Results

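MicroRNAs (miRNAs) were measured in fibro/adipogenic progenitors (FAPs), the stromal cells of skeletal muscle that can form fibroblasts and adipocytes. The 3 mouse libraries were 1 from normal muscle, 1 from muscle 5 days after cardiotoxin, a venom toxin that destroys muscle fibres and is followed by regeneration, and 1 from muscle 3 weeks after sciatic denervation, which leads to atrophy. The libraries held 4471365 counts (normal), 3636249 (cardiotoxin) and 7193088 (denervated). For folds, a count of 0 was taken as 3 counts, which is 0.671, 0.825 and 0.417 CPM, respectively. Folds given as at least a value rest on this level, and counting error allows smaller ones. Mature mouse miRNAs made up 99.0%, 98.4% and 99.1% of the counts. No difference below has a replicate check, and the 95% intervals in parentheses cover counting error only.

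In the normal library the most abundant miRNAs were miR-99a-5p at 70613 CPM, with an equal count in a row named miR-100-5p whose sequence matched the miR-99a gene only, followed by miR-125b-5p (58043 CPM), miR-27b-3p (48711 CPM) and miR-199b-3p (44648 CPM). The denervated library shared most of this profile, with miR-125b-5p at 55358 CPM, miR-99a-5p at 54157 CPM and miR-199b-3p at 49642 CPM. Its highest single row was that of miR-21a-5p at 103762 CPM. The miR-99a-5p and miR-100-5p rows again had equal counts. If the reads of their sequence were split between these rows, their summed level would lie above miR-21a-5p. In the cardiotoxin library, miR-21a-5p alone held 53.9% of all counts (538721 CPM), against 2.14% in normal and 10.4% in denervated. The next in the cardiotoxin library were miR-27b-3p (34967 CPM), let-7i-5p (25078 CPM), let-7g-5p (17499 CPM) and miR-30d-5p (16022 CPM). miR-21a is a miRNA induced in many injured tissues, and its gene lies on the minus strand of chromosome 11 from 86584067 to 86584158 (GRCm38), inside Vmp1.

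The comparison of cardiotoxin with normal asked how the miRNA profile of cells labelled as FAPs differed during muscle regeneration. In the library labelled cardiotoxin, most miRNAs of mesenchymal cells, to which FAPs belong, were far below normal and those of leukocytes far above. How far its values are those of FAPs is therefore not settled by these data. Of 446 items, 144 were at least 2-fold higher in the cardiotoxin library and 176 at least 2-fold lower. Among the 200 mature miRNAs with the highest mean, the 3 highest ratios belonged to miRNAs of blood leukocytes. miR-223-3p, a myeloid miRNA, was at 5406 CPM against 7.38 in normal, which was 732-fold higher (521 to 1064). miR-142a-3p, present across blood cell lineages, was 511-fold higher (358 to 757), and miR-142a-5p was 148-fold higher (128 to 173). Many of the lowest ratios belonged to miRNAs of mesenchymal cells and of the imprinted Dlk1-Dio3 region, with the epithelial miR-205-5p and miR-218-5p also among the 12 lowest. miR-199b-5p, a mesenchymal miRNA at 12015 CPM in normal, was 526-fold lower (425 to 661).

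All 8 leukocyte miRNAs were at least 2-fold higher in the cardiotoxin library, with a median log2 ratio of 7.47 (7.76 with members at a count of 0 set to their bound) at percentile 100 of random lists. miR-342-3p was 30.8-fold higher (29.0 to 32.8) and miR-150-5p, a lymphocyte miRNA, 13.3-fold higher (12.2 to 14.6). miR-223-5p and miR-511-3p, both at a count of 0 in normal, were at least 378-fold and 325-fold higher. The inflammation list had 5 of 9 members higher and 1 lower, with a median of 2.31 at percentile 99.8. Its members included miR-21a-5p, 25.1-fold higher (25.0 to 25.3), miR-146a-5p, 8.52-fold higher, and miR-125a-5p, 12.4-fold lower. miR-21a-3p, from the other arm of the same hairpin, was 11.8-fold higher (10.4 to 13.5).

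Of the 11 mesenchymal miRNAs, 10 were at least 2-fold lower and miR-10a-5p was 7.41-fold higher, with a median of -6.45 at percentile 0.085. The 11 include the miR-100-5p row, which repeats miR-99a-5p, and without it 9 of 10 were lower with a median of -6.45. miR-199a-5p was 166-fold lower (154 to 178), miR-199b-3p 184-fold lower (172 to 197) and miR-214-5p, at a count of 0 in cardiotoxin, at least 482-fold lower. miR-99a-5p was 49.0-fold lower and miR-125b-5p 87.4-fold lower. The decreases were uneven, the smallest being those of miR-10b-5p (3.06-fold, log2 ratio -1.62) and miR-22-3p (2.49-fold, log2 ratio -1.32). The total without miR-21a-5p, which moved the median of all items by 1.04, would bring both within 2-fold. All 44 kept members of the list for the Dlk1-Dio3 region on chromosome 12 were at least 2-fold lower, with a median of -5.97 (-6.16 with the 13 members at a count of 0 set to their bound) at percentile 0. The 12 kept miRNAs placed in the region but not on the list, among them miR-329-5p and miR-1247-5p, were all lower too. miR-127-3p was at 18290 CPM in normal and 116 in cardiotoxin, which was 158-fold lower (144 to 175). miR-127-5p was 396-fold lower (169 to 1220, from 5 counts), miR-329-5p 203-fold lower (134 to 324), miR-136-3p 183-fold lower (131 to 265), miR-434-5p 184-fold lower (127 to 278) and miR-485-5p at least 253-fold lower.

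The smooth muscle and pericyte list, made of miR-143 and miR-145a arms, was lower in all 4 members. Its median of -2.68 stood at percentile 23.45, within the spread of random lists, and miR-143-3p was 5.33-fold lower. The miR-17-92 clusters, which favour proliferation, were higher in 9 of 10 members with a median of 2.91 at percentile 99.97. miR-20a-5p was 14.2-fold higher (13.1 to 15.4), miR-17-5p 10.4-fold higher (9.44 to 11.6) and miR-18a-5p 41.1-fold higher. All 3 kept members of miR-221 and miR-222 were higher (median 2.22, percentile 91.8), with miR-222-3p 8.10-fold higher and miR-221-3p 4.67-fold higher. Both endothelial miRNAs were higher, miR-126a-3p 3.62-fold and miR-126a-5p 3.37-fold. In the miR-34 family, which p53 can induce, miR-34a-5p was 23.9-fold higher (22.0 to 26.0), whereas miR-34c-5p was 15.0-fold lower and miR-34b-3p at least 28.5-fold lower. miR-7a-5p was 36.9-fold higher (33.4 to 40.8) and miR-339-5p 12.4-fold higher (11.6 to 13.3). At a count of 0 in cardiotoxin, miR-205-5p was at least 554-fold lower, miR-1247-5p at least 367-fold lower and miR-218-5p at least 244-fold lower.

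The adipogenesis-restraining list had 4 of 7 members higher, among them miR-206-3p at 9.77-fold, and miR-130a-3p 12.1-fold lower, with a median of 2.499 at percentile 99.95. Its median was -0.51 when only miRNAs with a mean of at least 100 CPM entered. The adipogenesis-promoting list had 3 of 8 members higher, such as miR-378a-3p (2.12-fold), and 3 lower, such as miR-30a-5p (5.70-fold), with a median of -0.21. The pro-fibrotic list had 3 of 8 higher and 4 lower, with a median of -1.01 that was 0.07 with miR-21a-5p left out of the totals. Its lower members include miR-199a-5p and miR-214-3p, which are also on the mesenchymal list, and its higher members include both miR-21a arms. The miR-181 family was at least 2-fold lower in 3 of 4 members (median -1.49 at percentile 42.6, and -0.41 with miR-21a-5p left out of the totals). The miR-15/16 family split, with miR-16-5p 2.53-fold higher and miR-497a-5p 36.3-fold lower (median 0.97). Epithelial members also went both ways (median 0.49), and the neural and glial list had 2 of 3 higher (median 1.44). Of the erythroid miRNAs, miR-451a was 4.30-fold higher and miR-486a-5p 1.22-fold higher, the latter marginally below normal with TMM factors.

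Median log2 ratios were smaller for the muscle fibre list (-0.36, with miR-206-3p and miR-133b-3p 9.77-fold and 2.98-fold higher, 0 of 5 members 2-fold lower and miR-1a-3p 1.34-fold lower), miR-29 (-0.49), the miR-322, miR-503 and miR-351 cluster (-0.18), let-7 (-0.46), miR-30 (-0.41) and miR-23/27/24 (-0.50). These 6 medians, and that of the adipogenesis-promoting list, turned positive when the 5 most abundant miRNAs or miR-21a-5p alone were left out of the totals. Leaving out miR-21a-5p moved the median of all items by 1.04 on the log2 scale and gave 220 items higher and 134 lower, while leaving out the 5 most abundant moved it by 0.76 and gave 196 and 140. The shifts were -0.28 with TMM factors and with the authors' signal, each giving 114 higher and 190 lower, and -0.17 with DESeq2 size factors, giving 122 and 185. In this library the leukocyte miRNAs stood far above normal beside each group described here.

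**Figure D1:**
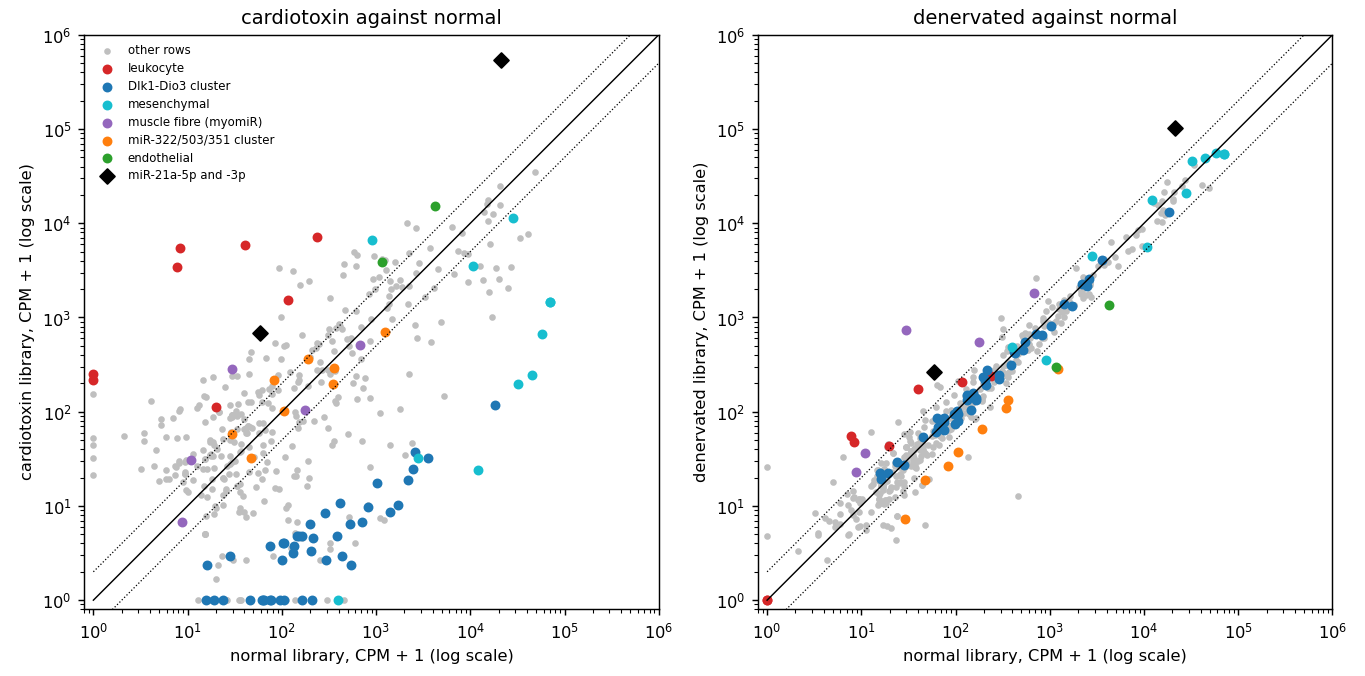
Level of each kept item (CPM + 1, log axes) in the cardiotoxin library (left) and the denervated library (right) against the normal library, 1 library each. The solid line marks equal levels and dotted lines 2-fold differences. Leukocyte miRNAs lie above and Dlk1-Dio3 miRNAs below the dotted lines on the left, while all 44 listed Dlk1-Dio3 miRNAs lie within them on the right.

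The comparison of denervated with normal asked how the miRNA profile of cells labelled as FAPs differed in muscle without its nerve. Far fewer items were apart here, with 28 at least 2-fold higher, 28 at least 2-fold lower and 390 within 2-fold. Among the 200 mature miRNAs with the highest mean, the highest ratio was that of miR-206-3p, a skeletal muscle miRNA, at 728 CPM against 28.9, which was 25.2-fold higher (21.2 to 30.3). miR-21a-5p was 4.84-fold higher (4.81 to 4.88) and miR-21a-3p 4.55-fold higher (3.996 to 5.21). The lowest was miR-205-5p, an epithelial miRNA, at 11.8 CPM against 457, which was 38.7-fold lower (31.1 to 48.7). The miR-322, miR-503 and miR-351 cluster and both endothelial miR-126a arms were also lower. Several of these miRNAs are those of muscle fibre, epithelial or endothelial cells. How far the differences are those of FAPs is therefore not settled by these data.

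All 5 kept muscle fibre miRNAs were at least 2-fold higher in the denervated library, with a median of 1.64 at percentile 99.86. Besides miR-206-3p, miR-133a-3p was 3.12-fold higher (2.89 to 3.38), miR-1a-3p 2.68-fold higher (2.58 to 2.79) and miR-133b-3p, whose sequence also matches the miR-133a genes, 3.55-fold higher (2.59 to 5.04). The miR-206 gene lies on chromosome 1 from 20679010 to 20679082 (GRCm38). Of the leukocyte list, 4 of 8 members were higher, with a median of 0.98 at percentile 99.96. 2 of the 8, miR-223-5p and miR-511-3p, had a count of 0 in both libraries and were kept for their level in cardiotoxin. The median was 2.12 over members with a mean of at least 100 CPM, but that mean includes cardiotoxin too. Through it passed miR-223-3p (7.38 CPM in normal, 47.3 in denervated) and miR-142a-3p (6.71 and 54.8 CPM). miR-142a-3p was 8.16-fold higher (5.63 to 12.3), miR-223-3p 6.40-fold higher (4.47 to 9.46) and miR-142a-5p 4.42-fold higher (3.77 to 5.199), whereas miR-342-3p differed by 1.01-fold (0.938 to 1.10). The inflammation list had 3 of 9 members higher (median 0.66, percentile 99.96), among them miR-146b-5p at 2.34-fold (2.21 to 2.49).

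All 8 kept members of the miR-322, miR-503 and miR-351 cluster were at least 2-fold lower, with a median of -1.60 at percentile 0. The cluster lies on the minus strand of chromosome X, with the measured genes from 53047997 to 53054349 (GRCm38). miR-351-5p was 4.38-fold lower (4.16 to 4.61), miR-503-5p 3.21-fold lower (2.68 to 3.86), miR-322-3p 3.17-fold lower (2.91 to 3.46), miR-322-5p 2.97-fold lower (2.64 to 3.33) and miR-450a-5p 2.73-fold lower (2.52 to 2.96). miR-126a-5p and miR-126a-3p, made from an intron of Egfl7 on chromosome 2, were 3.83-fold lower (3.64 to 4.03) and 3.13-fold lower (3.05 to 3.21). In the epithelial list, 4 of 5 members were lower (median -2.43, percentile 0.055), including miR-200a-3p at 8.85-fold lower (6.24 to 12.9), while miR-203-3p was 1.25-fold higher.

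In the miR-34 family, miR-34c-5p was 3.66-fold higher (3.53 to 3.81) and miR-34b-3p 3.29-fold higher (2.67 to 4.10), while miR-34a-5p was 1.15-fold lower (1.04 to 1.29). miR-1247-5p, made from inside Dio3os in the Dlk1-Dio3 region, was 3.24-fold higher (3.05 to 3.43) and miR-15b-5p 2.68-fold higher (2.37 to 3.05). miR-10a-5p was 2.54-fold lower (2.42 to 2.67). miR-27b-3p was 2.05-fold lower (2.04 to 2.07) and miR-326-3p 2.04-fold lower (1.86 to 2.24). These last were under 2-fold with each of the other scalings, miR-27b-3p at a log2 ratio of -0.91 and miR-326-3p at -0.90 in the total without miR-21a-5p. The miR-17-92 clusters had 1 of 10 members at least 2-fold higher, with a median of 0.72 at percentile 99.93. miR-31-5p, at a count of 0 in normal and 24.9 CPM in denervated, was at least 37.1-fold higher.

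Most mesenchymal and Dlk1-Dio3 miRNAs, far below normal in the cardiotoxin library, lay close to normal in the denervated library. None of the 44 members of the Dlk1-Dio3 list was 2-fold apart (median -0.03), and 1 of 11 mesenchymal members was lower (median -0.07, or 0.04 without the miR-100-5p row). Of the 12 miRNAs of the region not on the list, only miR-1247-5p was 2-fold apart. The list medians were slightly above 0 with TMM factors, DESeq2 factors, the authors' signal and the total without miR-21a-5p, as was that of miR-15/16 (-0.09). miR-199a-5p was 1.43-fold higher and miR-214-3p 1.60-fold higher. The smooth muscle and pericyte list (median -0.72), miR-23/27/24 (-0.48) and miR-181 (-0.47) were lower, at percentiles 1.62, 1.57 and 2.44, with at most 1 member each at 2-fold. miR-29 (0.41), miR-30 (-0.26), let-7 (0.16), the pro-fibrotic list (0.15), the adipogenesis-promoting list (0.03), miR-221 and miR-222 (-0.15) and the neural and glial list (-0.03, positive with each other scaling) stood near normal. The adipogenesis-restraining list had 3 of 7 members higher and miR-27b-3p lower (median 0.50, and -0.33 over members with a mean of at least 100 CPM). miR-451a was 4.18-fold higher and miR-486a-5p 1.27-fold higher. Scaling moved the median of all items by at most 0.11 on the log2 scale here, and no H19 or Igf2 hosted miRNA passed the filter.

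**Figure D2:**
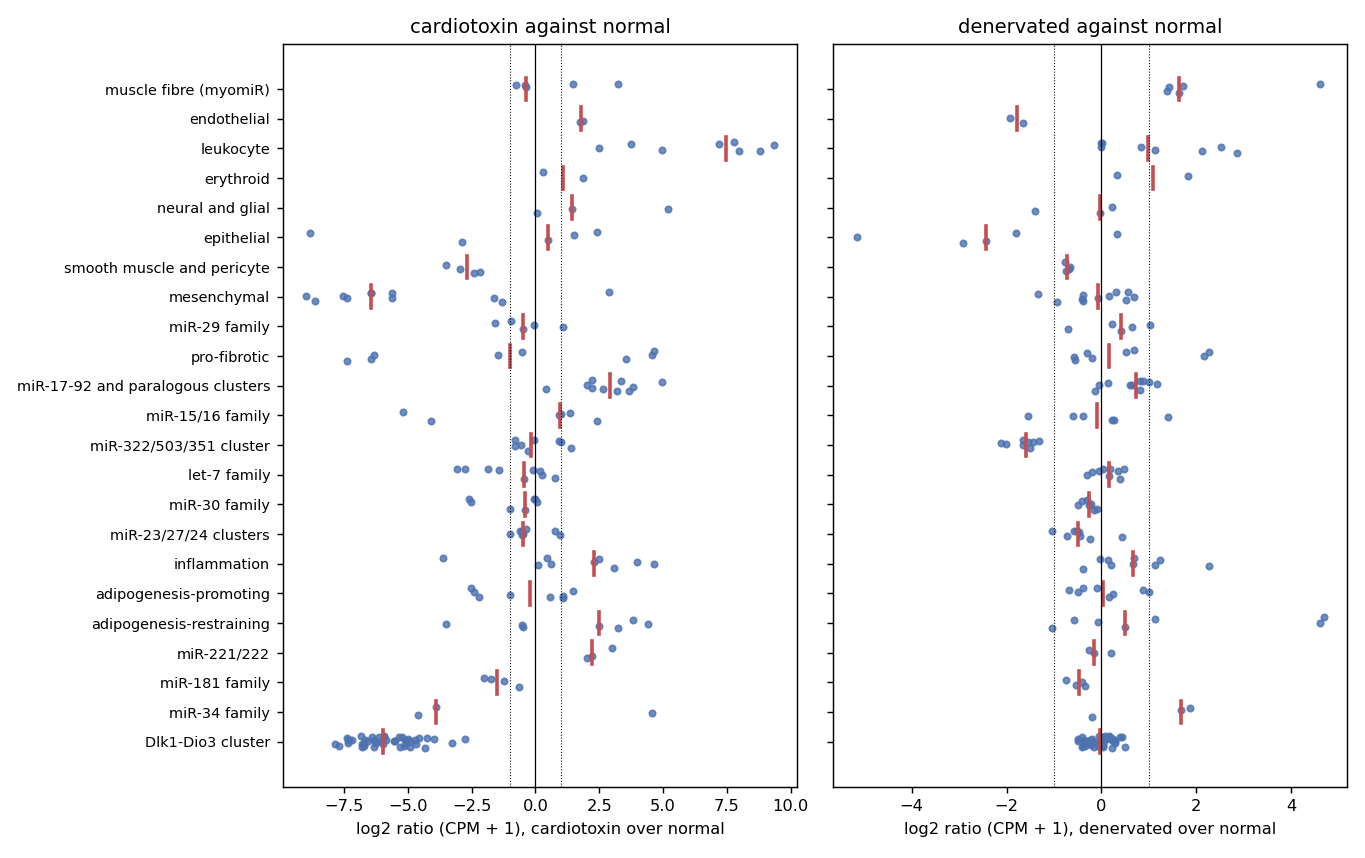
Log2 ratio (CPM + 1) of each kept list member against normal in the cardiotoxin library (left) and the denervated library (right), 1 library each, with the x axes on different ranges. Each point is a miRNA, red bars are list medians and dotted lines mark 2-fold. Leukocyte, mesenchymal and Dlk1-Dio3 medians reach 7.47, -6.45 and -5.97 on the left, and the medians of the muscle fibre list and the miR-322, miR-503 and miR-351 cluster reach 1.64 and -1.60 on the right.

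Cardiotoxin and denervated were set against each other to compare the injuries directly. Among the 200 mature miRNAs with the highest mean, 4 of the 6 with the highest ratios in cardiotoxin were leukocyte miRNAs, with miR-223-3p 114-fold higher (103 to 128), miR-142a-3p 62.6-fold higher (56.6 to 69.3), miR-142a-5p 33.6-fold higher (31.7 to 35.6) and miR-342-3p 30.4-fold higher (28.9 to 31.9). miR-7a-5p was 37.5-fold higher (34.7 to 40.7) and miR-34a-5p 27.6-fold higher (25.7 to 29.7). In the other direction, miR-1247-5p was at least 1188-fold lower in cardiotoxin, miR-214-5p at least 595-fold lower, miR-199b-5p 776-fold lower (626 to 974), miR-127-5p 401-fold lower (172 to 1236), miR-199a-5p 236-fold lower (219 to 254) and miR-199b-3p 205-fold lower (192 to 219). All 44 members of the Dlk1-Dio3 list and 8 of 11 mesenchymal members were lower in cardiotoxin. All 8 leukocyte members, 9 of 10 miR-17-92 members and 6 of 8 members of the miR-322, miR-503 and miR-351 cluster were higher in cardiotoxin, the last with a median of 1.38 that was just under 2-fold with TMM factors (0.996) and with the authors' signal (0.989). The muscle fibre list was lower in cardiotoxin in 4 of 5 members, with a median of -1.76 (percentile 24.2) that was -0.89 with miR-21a-5p left out of the totals. In total, 150 items were higher and 172 lower in cardiotoxin. That split was 110 and 191 with TMM factors, 110 and 192 with the authors' signal, 200 and 142 without the 5 most abundant miRNAs and 212 and 135 without miR-21a-5p.

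18 items were at least 2-fold higher than normal in both conditions. miR-21a-5p, miR-21a-3p, miR-223-3p, miR-142a-3p, miR-142a-5p, miR-146b-5p, miR-155-5p, miR-206-3p and miR-15b-5p were among them. Only miR-205-5p and miR-10b-3p were at least 2-fold lower in both with this scaling. Independent lists of these sizes would share 9.04 higher and 11.0 lower items, and counting noise around the shared normal library gave a mean of 0.024 and 0.004. That simulation held no true differences, so few shared items had to result and it is no yardstick for the observed overlap. 5 items were higher in denervated and lower in cardiotoxin, and 10 were lower in denervated and higher in cardiotoxin. miR-34c-5p and miR-1247-5p were of the first kind and miR-126a-3p, miR-126a-5p and miR-10a-5p of the second. Both comparisons used the same normal library, so part of any excess may come from it.

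**Figure D3:**
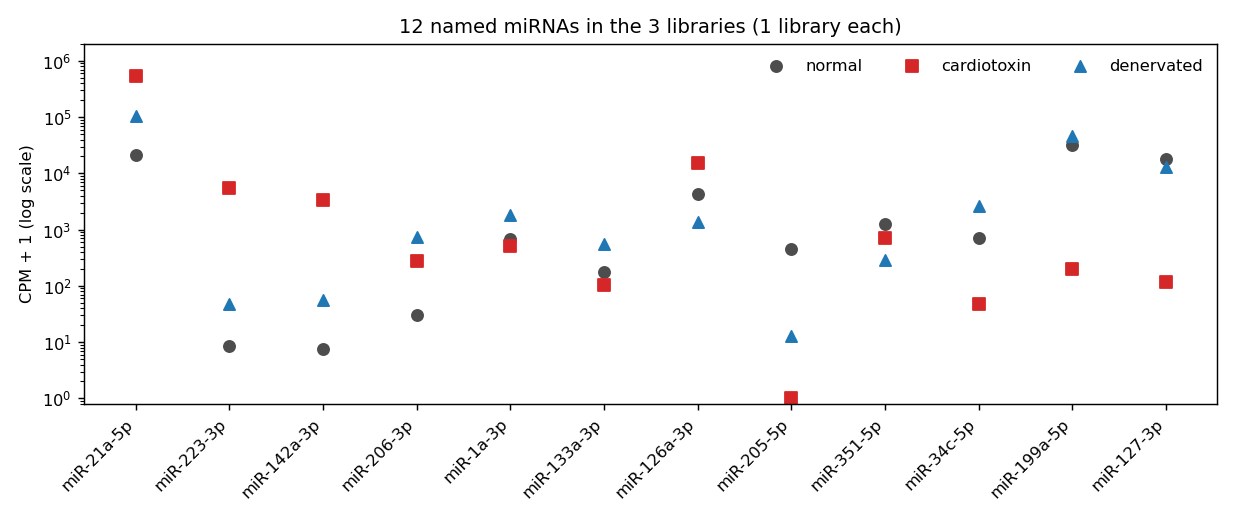
Levels (CPM + 1, log axis) of 12 named miRNAs in the normal, cardiotoxin and denervated libraries, 1 library each. miR-21a-5p was highest in cardiotoxin (538721 CPM), miR-206-3p was highest in denervated (728 CPM), and miR-199a-5p and miR-127-3p were lowest in cardiotoxin (195 and 116 CPM).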

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

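No paired analysis was possible because each condition had 1 library. The total without miR-21a-5p, the filter on normal and denervated alone and the mesenchymal list without the miR-100-5p row were chosen after seeing the data. Of 135 recomputed counts of items, 106 stayed within 1.5 times the reported count. Without a filter on low values, 702 items were at least 2-fold apart between cardiotoxin and normal (342 higher, 360 lower), 237 between denervated and normal (109 higher, 128 lower) and 658 between cardiotoxin and denervated (340 higher, 318 lower), and 121 were apart from normal the same way in both conditions (42 higher, 79 lower). With a mean of at least 100 CPM these counts were 154 (60 higher, 94 lower), 25 (13 higher, 12 lower), 153 (60 higher, 93 lower) and 9 (8 higher, 1 lower). Each filter admits a different number of items, but that alone need not give these differences. Without a filter, items with a few counts in normal and 0 in the other libraries count as lower in both conditions. PC-3p-63978_7, with 7 counts in normal, had a log2 ratio of -1.36 in both. Leaving miR-21a-5p out of the totals gave 220 items higher in cardiotoxin than in normal, because it raises every cardiotoxin ratio alike. Items lower than normal in both conditions numbered 4 with TMM factors, 4 with the authors' signal, 1 without the 5 most abundant miRNAs and 1 without miR-21a-5p. The share of higher among all 2-fold items between cardiotoxin and normal was 45% as reported, 37.5% with TMM factors and with the authors' signal, 39.7% with DESeq2 factors, 58.3% without the 5 most abundant and 62.1% without miR-21a-5p. Between cardiotoxin and denervated it was 46.6% as reported, 36.5% with TMM factors, 36.4% with the authors' signal, 58.5% without the 5 most abundant and 61.1% without miR-21a-5p.

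Of 618 recomputed list medians, 16 fell below 2-fold where the reported median had reached it, among them 2 that reversed. The pro-fibrotic median for cardiotoxin against normal was 0.0704 without miR-21a-5p, and the adipogenesis-restraining median was -0.51 with a mean of at least 100 CPM, a filter that leaves fewer members. The neural and glial median for cardiotoxin against normal, 1.44 as reported, was 0.97 without a filter. None of 590 recomputed log2 ratios of miRNAs named by their ratio reversed, and 11, all of miR-27b-3p or miR-326-3p, fell below 2-fold. Depth limits what can be said of miRNAs near 0.825 CPM in the cardiotoxin library, the shallowest of the 3.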

Other observations

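Several sets of neighbouring miRNA genes differed from normal in the same direction. In the cardiotoxin library, the miR-224 and miR-452 genes on chromosome X had a mean log2 ratio of -5.13 against normal, and miR-497 with miR-195a on chromosome 11 had -4.63. The miR-99b, let-7e and miR-125a genes on chromosome 17 had a mean of -2.96. In the other direction, the miR-182 and miR-183 genes, known from sensory and epithelial cells, had a mean of 1.57. The 5 genes from miR-500 to miR-532 on chromosome X were uneven, from 0.14 to 2.88. In the denervated library, miR-182 with miR-183 had a mean of -1.29 and miR-200a with miR-200b -2.68, next to 1.77 for miR-34c with miR-34b. The miR-224 and miR-452 genes stood at 0.18 there, close to normal.

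The let-7 family, within 2-fold of normal in the denervated library, was uneven in the cardiotoxin library. let-7b-5p was 8.51-fold lower than normal and let-7e-5p 6.85-fold lower, while let-7g-5p was 1.14-fold higher and let-7i-5p 1.21-fold higher. The miR-30 family showed the same kind of spread, with miR-30a-5p 5.70-fold lower and miR-30d-5p 1.05-fold higher. With TMM factors, let-7g-5p, let-7i-5p and miR-30d-5p were at or slightly below normal (log2 ratios of -0.10, -0.02 and -0.21). let-7g-5p, let-7i-5p and miR-30d-5p were the 3 most abundant after miR-21a-5p and miR-27b-3p in that library.

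The tests below were chosen after the results were seen, except that of neighbouring genes, whose prediction was written before its result was seen. Genes within 10 kb of each other on a strand are often cut from a shared transcript, which would give their miRNAs like ratios. Over 26 such clusters with 95 genes, the mean SD of log2 ratios within a cluster was 0.20 for denervated against normal, while shuffling the miRNAs over clusters gave a mean of 0.56 and never less than 0.35 in 10000 draws. For cardiotoxin against normal the mean SD was 0.72, with a shuffled mean of 2.93. A shared transcript per cluster may account for this, although reads shared between similar members of a cluster were not excluded.

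Most mesenchymal miRNAs and the Dlk1-Dio3 miRNAs were far below normal in the cardiotoxin library. Crowding by a few abundant miRNAs is argued against, since the mesenchymal median came no closer to 0 than -5.36 under 6 scalings. A lower share of progenitors with all other cell types in fixed proportion is argued against as well, because the leukocyte median lay 7.84 above that of the muscle fibre list on the log2 scale. RNA of leukocytes may be part of the library, as 8 of 8 leukocyte miRNAs were at least 2-fold above normal with miR-342-3p at 7220 CPM and miR-142a-5p at 5833 CPM; 6 of the 8 were also detected in normal, miR-155-5p stands on other lists too, and whether a sort removed leukocytes is not given in the sources used here. A change within the progenitors cannot be told apart from dilution, since the median of the 30 Dlk1-Dio3 members at 100 CPM or more in normal (-6.32) lay 1.20 above that of 5 miR-199 and miR-214 miRNAs (-7.52) and either would lower both, and that another cell population was sequenced in place of progenitors also stays open, as untested.

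Muscle fibre miRNAs were above normal in the denervated library. More RNA of muscle fibres may explain miR-1a-3p, miR-133a and miR-133b-3p, whose 4 log2 ratios lay within 0.34 of each other. That closeness cannot decide it, because the 4 are not independent. Both miR-133a arms come from the same hairpins, and the miR-133b-3p sequence also matches the miR-133a genes. The miR-1a-2 and miR-133a-1 genes lie in a shared host gene. If each normal level came from fibres alone, the same amount of unchanged fibre RNA would not give the ratio of miR-206-3p. That ratio lay 2.88 above the highest of these 4. Whether miR-206-3p and these 4 came from fibres alone in normal was not tested. A higher level of miR-206-3p within denervated fibres or in other cells stays open, as untested.

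miR-21a-5p was above normal in the denervated library, where scaling is argued against, since its log2 ratio was 2.28 or more under 6 scalings, and so are reads of near-identical copies, since miR-21a-3p from the other arm had 2.17. Leukocyte RNA was weighed as a share of RNA like the whole cardiotoxin library. That library's differences from normal were taken as those that leukocytes bring, which was not tested. For miR-21a-5p, such RNA would have to make up 15.9% of the denervated library. Under that assumption, leukocyte RNA is argued against as the whole cause. The 8 leukocyte miRNAs gave a median share of 1.07% (0.969 to 1.19, counting error only), and 7 of them, such as miR-223-3p at 47.3 CPM where 867 would be needed, stayed below the level needed by more than counting error, while miR-155-5p gave 25.8%. The bound on this median replaced earlier criteria also set after the shares were seen, under which the outcome had been left open (the needed share lay inside the range of single miRNAs, and 4 of the 5 most abundant, not miR-150-5p, were over 2-fold short). Leukocytes with another miRNA profile and a higher level within the progenitors stay open, as untested.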
